A study of Homo sapiens with 30 samples.

How the data were processed

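The series holds 30 libraries from HT1080, a human fibrosarcoma cell line, taken at passages 10 to 15. Of these, 18 are global run-on (GRO-seq) libraries, in which nuclei extend engaged transcripts with bromouridine and the labelled RNA is sequenced. They form 6 groups of 3: WT, hNABP2 KO and hNABP1 KO, each run with nucleotides (with NTP) and without them (no NTP). Another 4 are ChIP-seq libraries of WT cells, 2 with anti-hNABP2 antibody and 2 with IgG. The last 8 are DRIP-seq libraries, in which the S9.6 antibody pulls down RNA:DNA hybrids, from WT and hNABP2 KO cells with and without RNase H, 2 per group. The labels mention 2 independent experiments where 3 run-on repeats are given. How far the 3 are independent is not given in the sources used here, so n, SD and permutation p count libraries. hNABP2 (hSSB1, gene NABP2) and hNABP1 (hSSB2, gene NABP1) are single-stranded DNA binding proteins that share the SOSS complex with INTS3 and INIP.

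The deposited count table gives raw counts per gene symbol for the 18 run-on libraries, with no normalization by the authors. The deposited peak lists give a fold, the ratio of the summit over local background, and -log10 p and -log10 q values for each peak, in the layout that MACS2 writes. The list of anti-hNABP2 ChIP repeat 1 gives only the -log10 q at the summit, and its fold and -log10 p come from the deposited annotation of its peaks. Peak lists of 15 libraries were used: 2 anti-hNABP2 ChIP, 9 run-on with NTP and 4 DRIP without RNase H. No values of the IgG or RNase H libraries were analysed here. The authors name cutadapt 1.18, Bowtie2 2.3.5, SAMtools and MACS2 2.2.1 with the hg38 build, without their order or settings. The strand setting of the counting, the control libraries of the peak calling and the kind of knockout are not given in the sources used here. Positions below are hg38. The deposited annotation tables of the ChIP and DRIP peaks assign a nearest gene to each peak they hold, and promoters are peaks annotated within 1 kb of a start. They lack 13 and 16 peaks of ChIP repeats 1 and 2 and 1 to 15 peaks per DRIP library, most of them on unplaced contigs.

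Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Run-on counts were compared with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The library sizes in these fits were the sums over the genes that passed the filter. The log2 fold changes are therefore not on the scale of CPM per library total and can differ from it. The 3 genotypes were compared in 1 model of the 9 libraries with NTP. The effect of NTP within each genotype, and the difference of that effect between genotypes (the interaction), were tested in 1 model of all 18 libraries. DESeq2 1.42.0 and limma 3.58.1 (voom) were run beside edgeR. In each genotype contrast the named genes were to be the largest changes past the threshold; with fewer than 5 past it, the 5 genes with the smallest p in each direction are named and said not to pass. For peaks, the 5 with the highest score among those shared by the repeats, or by a pair of assays, are named.

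Repeat numbers were tested as pairs. With group means removed, each of the 9 same-number pairs of libraries correlated at 0.563 to 0.843 and the different-number pairs at -0.690 to 0.119, so the numbers pair the samples. The fit without the pairs stays as fixed beforehand; the paired fit is the replicate block alternative.

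Gene lists were tested with camera (preset inter-gene correlation 0.01) where at least 5 members passed the count filter, with an estimated correlation and with fry beside it. They cover the target genes, SOSS and Integrator subunits, Pol II pausing and elongation factors, R-loop and helicase factors, the DNA double-strand break and replication stress response, p53 targets, immediate early, heat shock, ATF4 and unfolded protein response, interferon-stimulated, NF-kB, hypoxia and glycolysis, cholesterol synthesis, extracellular matrix, S-phase, G2 and M, mesenchymal signalling, histone, cytosolic ribosomal protein, mitochondrially encoded and abundant non-coding RNA genes, and epithelial, leukocyte and neural markers. Because few genes passed the filter, each list was also given as its share of the counts of each library, compared with an exact permutation test, and tested among genes with 10 or more counts; both were chosen after seeing the data. For the promoters bound in ChIP, list membership was compared with Fisher's exact test, two-sided, and with 10000 random lists matched on run-on counts; this too was chosen after seeing the data.

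Overlaps between peak lists were counted with bedtools 2.31.1 at 1 bp or more and set beside 100 random placements on the same chromosomes. Shares of peaks carry exact Clopper-Pearson 95% intervals. Peak numbers and shares of the 3 genotypes were compared with two-sided exact permutation tests. In these, 3 libraries against 3 cannot give a p below 0.1, and 2 against 2 cannot go below 0.333. All permutation tests here, those of the gene lists included, exchange libraries across repeats and leave out the pairing by repeat number. Their p values and smallest possible values are therefore not exact for paired libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

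Run-on libraries held 5272 to 164357 gene counts, so that a floor of 3 counts corresponds to 18.3 to 569 CPM, the count scaled to the library total. Intervals and floors cover counting error only. The pipeline was tested on simulated data with the measured depth and spread of the libraries. Of the gene symbols, 28 had been turned into dates and were left as they are. The alternatives tried were other normalizations, filters, tools and models, leaving out each library in turn, stricter peaks and stricter or wider overlaps, and peaks off the contigs and the mitochondrial genome.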

Results

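Global run-on sequencing, anti-hNABP2 ChIP-seq and DRIP-seq were measured in HT1080 fibrosarcoma cells. The labels name WT cells and knockouts of 2 single-stranded DNA binding proteins, hNABP2 (hSSB1) and hNABP1 (hSSB2). Run-on libraries with NTP held 11981, 5883 and 164357 counts in WT repeats 1 to 3. Those labelled hNABP2 KO held 19581, 6581 and 115923, and those labelled hNABP1 KO held 11091, 7553 and 115528. Without NTP the totals were 9220, 5272 and 19247 in WT, 10544, 8397 and 79429 in libraries labelled hNABP2 KO, and 6695, 6374 and 23865 in libraries labelled hNABP1 KO. Between 2402 and 20345 of the 26475 genes had a count in a library. The 2 ribosomal RNA genes RNA45S5 and RNA28S5 took 0.272% to 13.1% of the counts. In repeats 1 and 2 antisense genes held a median of 67.9% of the counts of 304 pairs of a gene and its antisense gene, and 186 of the pairs had more antisense counts. VIM-AS1 had 4636 counts and VIM 69, while TTN-AS1 had 1 and TTN 291. Counts of sense and antisense genes below are therefore given without a statement on their strand, those of the target genes and gene lists included. In repeat 3 the median was 32.4% over 781 pairs.

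**Figure D1:**
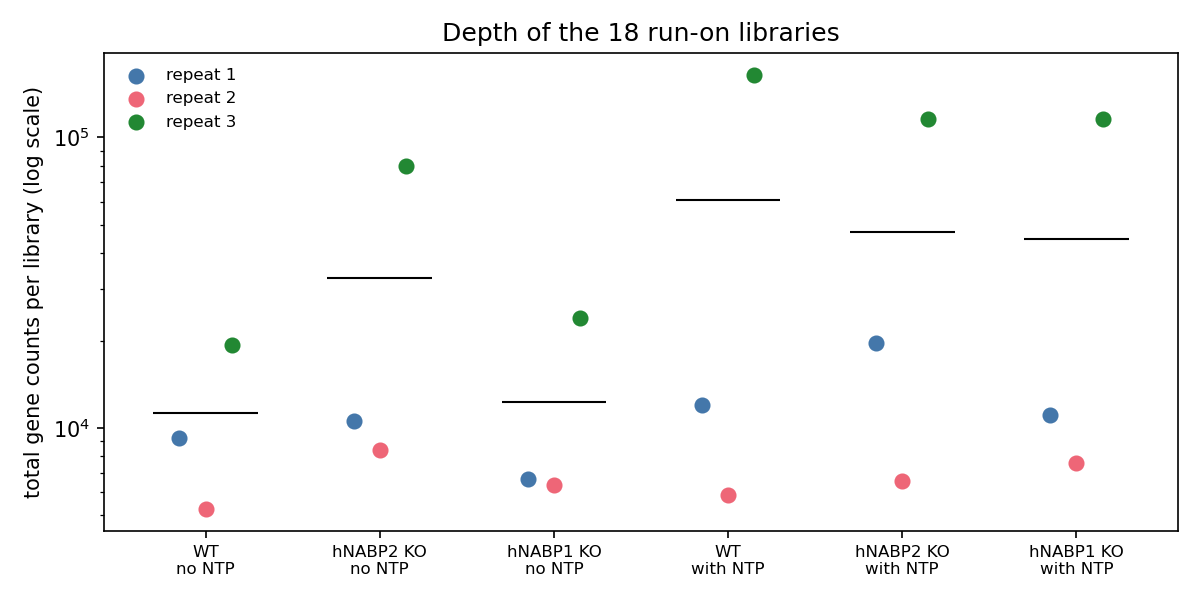
Total gene counts (log scale) of the 18 run-on libraries by group; points are libraries coloured by repeat and lines are group means. Repeat 3 is the deepest library in each of the 6 groups, with 164357 counts in WT with NTP against 5883 in repeat 2.

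**Figure D2:**
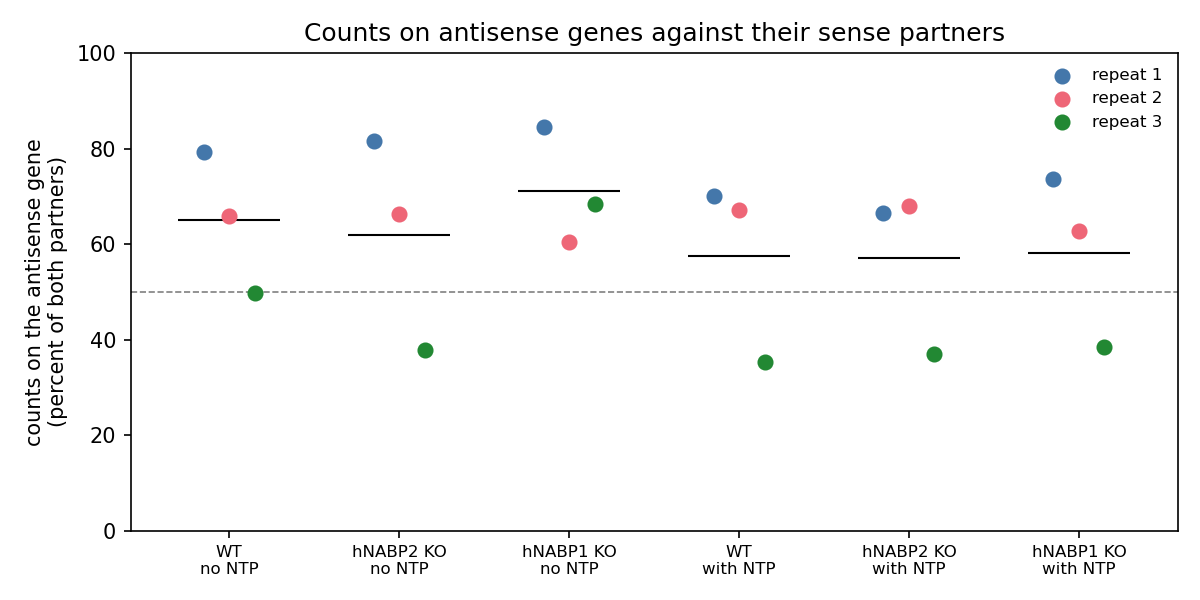
Counts on antisense genes as percent of the counts of both partners, per run-on library; points are libraries coloured by repeat, lines are group means and the dashed line marks equal counts. Repeats 1 and 2 lie at 60.5% to 84.6%, and repeat 3 at 35.4% to 49.8% except for the library labelled hNABP1 KO without NTP at 68.3%.

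The 2 target genes come first. NABP2 had 4, 0 and 8 counts in WT repeats 1 to 3 with NTP (128 ± 180 CPM, SD, n = 3), 4, 3 and 15 in the libraries labelled hNABP2 KO (263 ± 171 CPM) and 0, 0 and 6 in those labelled hNABP1 KO (17.3 ± 30.0 CPM). NABP1 had 1, 0 and 19 counts in WT (66.4 ± 59.7 CPM), 2, 0 and 9 in libraries labelled hNABP2 KO (59.9 ± 53.3 CPM) and 0, 1 and 18 in those labelled hNABP1 KO (96.1 ± 84.0 CPM). Without NTP, NABP2 summed to 2, 8 and 1 counts over the 3 repeats in WT and in libraries labelled hNABP2 KO and hNABP1 KO, and NABP1 to 1, 5 and 2. With NTP, the mean CPM of neither gene was below WT in the libraries that bear its knockout label, though in repeat 1 both were (NABP2 204 against 334 CPM, NABP1 0 against 83.5 CPM). The kind of knockout is not given in the sources used here, and the genotypes below are those of the labels. With the strand open in repeats 1 and 2, these counts do not settle the genotype.

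The first comparison asks which genes the loss of hNABP2 changes in nascent transcription. DLG4, a synaptic scaffold gene, had fewer counts in each of the 3 libraries labelled hNABP2 KO (9, 6 and 14) than in the WT library of the same repeat (15, 12 and 32), at a log2 fold change of -1.16 (SE 0.489, adjusted p = 0.989 by edgeR), and did not pass. The uncharacterised LOC100130093 lay at 0.84 (SE 0.581), NEIL1, a base excision repair glycosylase, at 0.98, and ADCY3, an adenylate cyclase, at 0.76. SAMD11 (0.64) and MCM3AP-AS1 (0.51) complete the 5 smallest p values among the higher genes. On the lower side FADS2, a fatty acid desaturase, lay at -0.94, the sphingomyelinase SMPD4 at -0.88, RMRP, the RNA of RNase MRP, at -0.78 and RNA28S5, the 28S ribosomal RNA, at -1.16. None of these 10 genes passed. Of 129 genes tested by edgeR, 0 changed in libraries labelled hNABP2 KO; 1 had an unadjusted p under 0.05, where chance gives 6.45 for libraries that are not paired, and DESeq2 and voom also called 0. The smallest adjusted p was 0.989. In 3 of the 129 genes (2.33%) the groups did not overlap, where chance gives 10%, again for libraries that are not paired. The repeats pair these libraries, so neither number is an exact expectation here or below. In data simulated at this depth and spread the test recovered 0% of the 4-fold, 7.37% of the 8-fold and 16.8% of the 16-fold changes among the genes it could test. Counted over all changed genes, tested or not, it recovered 1.4% of the 8-fold and 4.4% of the 16-fold changes. With 10 or more counts per gene and the replicate block it recovered 3.43%, 16.5% and 45.3% of those tested, and 0% at each fold without the block. The first changes were drawn from the genes with the most counts and the others from a wider set, so the percentages are not comparable. The simulated genotypes shared the profile of each repeat, which favours the block.

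The second comparison sets hNABP1 KO, the paralogue, against WT. LOC100130093 was higher in CPM in each repeat (15, 22 and 13 counts against 7, 2 and 15) at a log2 fold change of 1.36 (SE 0.583, adjusted p = 1.00 by edgeR) and did not pass. TYMSOS, a transcript opposite the thymidylate synthase gene, lay at 1.23 and LOC100129046 at 1.02. LONP1, a mitochondrial protease, lay at 2.39 and the ribosomal precursor RNA45S5 at 2.81, both resting on repeat 3, where they had 200 and 5647 counts against 40 and 807 in WT. Lower values were found for MALAT1, an abundant nuclear non-coding RNA, at -1.37, WDR24, a subunit of the nutrient-sensing GATOR2 complex, at -1.37, FADS2 at -1.10, the cytoskeletal linker PLEC at -1.02 and DLG4 at -0.97. None of these passed either: edgeR called 0 of 129 genes, 1 had an unadjusted p under 0.05, and DESeq2 and voom called 0. The smallest adjusted p was 1.00, and 3 genes (2.33%) had groups that did not overlap against 10% by chance. With 10 or more counts per gene and the replicate block 6 genes were called, and 0 without repeat 3 of this label, as given below.

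Compared directly, libraries labelled hNABP2 KO had more MALAT1 counts than those labelled hNABP1 KO (log2 fold change 1.63, SE 0.776, adjusted p = 0.997 by edgeR; 867 ± 871 against 313 ± 297 CPM, SD, n = 3). FTSJ3, a ribosomal RNA methyltransferase, lay at 1.31, NEIL1 at 1.01, COL4A2-AS1 at 0.62 and SAMD11 at 0.56. The lower genes were RNA45S5 (-2.72), CCDC85B (-1.57), SMPD4 (-1.42), LOC100129046 (-1.26) and LINC01465 (-1.15). EdgeR called 0 of 129 genes, 0 had an unadjusted p under 0.05, and DESeq2 and voom called 0; the smallest adjusted p was 0.997. Groups did not overlap in 3 genes (2.33%, chance 10% without pairing). With 10 or more counts per gene and the replicate block 13 genes were called, and 0 without repeat 3 labelled hNABP1 KO. Across the 129 genes, which are not independent replicates, the effects in the 2 knockout labels correlated at r = 0.310 (Spearman's rho 0.328). Unchanged groups set against the same WT libraries gave a mean r of 0.497 in 100 simulations, with 95% of them from 0.339 to 0.640. These simulations leave out the pairing of the repeats, and their mean covariance of 0.442 lies far above the observed 0.0858, so they do not settle what the shared WT libraries contribute. With the replicate block r was 0.379. With 0 called genes for each label there was no overlap of calls to count.

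Libraries without NTP are the background of the run-on, and the comparison with NTP asks which genes depend on extension. In WT, RN7SK, the 7SK RNA that holds the elongation factor P-TEFb, had 2485 ± 1799 CPM with NTP and 13841 ± 18341 CPM without (SD, n = 3; log2 fold change -2.89, adjusted p = 0.997 by edgeR) and did not pass. This rests on 1 library: without NTP the repeats had 3471, 3035 and 35018 CPM, and in repeat 2 the value with NTP was higher (4420 CPM). Also lower were MIR7641-2 (-4.90), SNORA73A (-1.99), NUCB1-AS1 (-1.24) and DPP9-AS1 (-0.96), and higher were GNAI2, a G protein subunit, at 3.03, APTR (1.42), FAM69B (1.36), MBNL1-AS1 (1.33) and LRTOMT. MIR7641-2 rests on the same library, with 863 counts in repeat 3 without NTP and 0 in repeats 1 and 2. GNAI2 had 2, 0 and 22 counts with NTP against 0, 0 and 1 without, so it was under the floor of 3 counts outside repeat 3 with NTP. APTR (4, 6 and 39 against 1, 5 and 2) and MBNL1-AS1 (6, 4 and 36 against 1, 6 and 1) also had most counts in that library, the deepest. In libraries labelled hNABP2 KO, the fatty acid oxidation gene ACADVL lay at 1.56, the signal recognition particle RNA RN7SL1 at 3.26, AHNAK at 2.81, SNORA73A at 2.55 and TIPARP-AS1 at 1.31. RN7SL1, AHNAK and SNORA73A rest on repeat 1, with 54, 135 and 52 counts with NTP against 5, 11 and 6 without. FAM120AOS (-1.69), RMRP (-1.34), DPP9-AS1 (-1.01), LOC100129046 (-0.97) and COL4A2-AS1 (-0.89) were lower there. In libraries labelled hNABP1 KO, TIPARP-AS1 lay at 2.59 (SE 0.778, adjusted p = 0.779 by edgeR), RNA45S5 at 4.45, LONP1 at 3.07 and HCFC1R1 at 1.99, and ARMC5 was also higher. RNA45S5 rests on repeat 3 (72, 42 and 5647 counts with NTP against 66, 82 and 36 without). LONP1 had 3, 15 and 200 counts with NTP against 3, 8 and 16 without, and ARMC5 5, 6 and 86 against 2, 6 and 14. Repeat 3 held 115528 counts in total with NTP against 23865 without, so raw counts there differ by depth too. Set against the library totals, ARMC5 did not differ most in repeat 3. On that scale HCFC1R1 (6, 7 and 53 against 4, 1 and 17) was lower with NTP in repeats 1 and 3, so these rises depend on the normalization. FTSJ3 (-1.20), SPNS2 (-1.16), NUCB1-AS1 (-1.13), ACADVL (-1.02) and CTBP1-AS (-0.89) were lower. SPNS2 rests on repeat 3 without NTP (7, 24 and 16 counts with NTP against 6, 19 and 165 without). EdgeR called 0 of 211 genes in WT, 0 with the hNABP2 KO label and 0 with the hNABP1 KO label; 1, 2 and 7 genes had an unadjusted p under 0.05, where chance gives 10.6, and DESeq2 called 0 in each. Groups did not overlap in 2, 5 and 5 genes (0.948%, 2.37% and 2.37%; chance 10%). With the repeat number as a block, TIPARP-AS1 was the 1 gene called, in libraries labelled hNABP1 KO (log2 fold change 2.62, SE 0.601). That group's repeat 3 without NTP resembles the repeat 2 libraries, which puts its block in doubt, and without it TIPARP-AS1 lay at 1.88 (SE 0.723, adjusted p = 0.582 by edgeR) and was not called.

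Whether the knockout label changes the effect of NTP was tested as an interaction. For the hNABP2 KO label the genes with the smallest p were SNORA73A at a log2 difference of 4.53 (adjusted p = 0.997 by edgeR), RN7SL1 (3.90), MALAT1 (1.44) and the myosin genes MYH4 (2.86) and MYH1, with APTR (-1.52), FAM120AOS (-1.44), MBNL1-AS1 (-1.33), FAM69B (-1.30) and COL4A2-AS1 (-1.29) on the other side. For the hNABP1 KO label they were MIR7641-2 (6.01), RNA45S5 (4.27), LONP1 (2.97), RN7SK (2.70) and TIPARP-AS1 (2.46, adjusted p = 0.999 by edgeR), with GNAI2 (-3.74), MBNL1-AS1 (-1.67), ACADVL (-1.64), DND1 (-1.52) and FAM69B (-1.50) opposite. The values of SNORA73A, RN7SL1, MIR7641-2, RN7SK, RNA45S5 and LONP1 rest largely on single libraries: repeat 1 labelled hNABP2 KO with NTP for the first 2 genes, WT repeat 3 without NTP for the next 2, and repeat 3 labelled hNABP1 KO with NTP for the last 2. GNAI2 had few counts in WT outside repeat 3 with NTP, as given above. None of the genes passed: edgeR called 0 of 211 genes in each, 0 and 1 had an unadjusted p under 0.05, and DESeq2 called 0.

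Among the fixed gene lists, 1 had enough genes past the count filter to be tested, the abundant structural and nuclear non-coding RNAs with 6 members. Their median log2 fold change was -0.06 in libraries labelled hNABP2 KO (adjusted p = 0.197 by camera), where RN7SL1 lay at 1.31 and MALAT1 at 0.26, and 0.08 in those labelled hNABP1 KO (adjusted p = 0.365 by camera), where RMRP lay at -0.65 and RNA28S5 at 0.59. In the second case camera's direction was down, against the sign of the median. No member passed, over all genes tested or adjusted over the list alone (0 and 0 genes). In both labels the list was called by camera when 1 library was left out. Its median was -1.04 without hNABP2 KO repeat 1 and -0.80 without hNABP1 KO repeat 3, with adjusted p = 0.0926 and 0.161 by camera at an estimated correlation. Single tested members of other lists were FANCA, a Fanconi anaemia DNA repair gene (0.54 in libraries labelled hNABP2 KO and 0.53 in those labelled hNABP1 KO), KRT8 (-0.31 and -0.27), THBS1 (0.76 and 0.21), FN1 (0.66 and -0.13), COL5A1 (-0.32 and 0.26), HSP90AA1 (0.40 and 0.28) and the interferon regulator IRF7 (0.57 and 0.78), and none passed.

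As shares of all counts, S-phase genes held 0.159 ± 0.0535% in WT, 0.155 ± 0.0565% with the hNABP2 KO label and 0.277 ± 0.185% with the hNABP1 KO label (SD, n = 3). The last was above WT in 3 of 3 repeats (exact permutation p = 0.4, adjusted 0.968). Double-strand break response genes held 0.202 ± 0.0203%, 0.242 ± 0.0739% and 0.275 ± 0.0717%, above WT in 3 of 3 repeats for both labels (exact permutation p = 0.5 and 0.2), and hypoxia and glycolysis genes 0.185 ± 0.131%, 0.285 ± 0.248% and 0.337 ± 0.151%. Interferon-stimulated genes held 0.0967 ± 0.0653% in WT and 0.162 ± 0.101% with the hNABP2 KO label, higher in 3 of 3 repeats (exact permutation p = 0.5). Neural markers (0.0335 ± 0.0290% in WT) were also above WT in 3 of 3 repeats with the hNABP2 KO label, and SOSS and Integrator, cholesterol synthesis, heat shock and hypoxia genes with the hNABP1 KO label. Below WT in 3 of 3 repeats were p53 targets with both labels (0.169 ± 0.0429%, 0.126 ± 0.0728% and 0.140 ± 0.0360%), immediate early and histone genes with the hNABP2 KO label, and epithelial (0.167 ± 0.157% in WT) and leukocyte markers (0.0515 ± 0.00671% in WT) with the hNABP1 KO label. The exact permutation test cannot go below 0.1 here, so no list could pass; over the 23 lists with a count the adjusted p was 1 for each list with the hNABP2 KO label and at least 0.968 with the hNABP1 KO label. With 3 repeats, a list often falls on 1 side of WT in all of them by chance, and both labels share the WT libraries. The directions above are therefore descriptions only. The mitochondrially encoded list had 0 members in the count table.

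The ChIP comparison asks where hNABP2 lies on the genome of WT cells. Most peaks lay at promoters: 8981 of 10055 annotated peaks of repeat 1 (89.3%, 95% interval 88.7 to 89.9) and 2658 of 2816 of repeat 2 (94.4%, 93.5 to 95.2) were within 1 kb of a start. Within 1000 bp of a gene end of the RefSeq annotation lay 79.4% and 82.6% of the peaks, against 6.17% and 5.96% of random placements. Ranked by their score in repeat 1, the strongest shared peaks were at LAMP1, a lysosomal membrane protein gene (13, 113296801 to 113297443, fold 12.2, -log10 q 397), the kinase gene MKNK2 (19, 2050598 to 2051599, fold 12.1), TAF4, a TFIID subunit (20, 62065965 to 62066588, fold 14.0), the homeobox gene PKNOX1 (21, 42974490 to 42975400, fold 17.9) and PTMS (12, 6766227 to 6767159, fold 13.6). In repeat 2 they had folds of 3.85 (LAMP1) to 6.41 (MKNK2) and -log10 q of 4.38 (TAF4) to 9.34 (PKNOX1), where its medians were 5.87 and 4.54. Of the 2832 peaks of repeat 2, 2266 (80.0%, 78.5 to 81.5) overlapped 1 of the 10068 peaks of repeat 1, against 0.321% of random placements, and 22.6% of repeat 1 peaks overlapped repeat 2. Promoter peaks named 7638 genes in repeat 1, 2427 in repeat 2 and 2062 in both. NABP2 (fold 4.50) and NABP1 (fold 4.73) had a promoter peak in repeat 1 and INTS6 in both repeats. No values of the IgG libraries were analysed here.

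Promoters bound in both repeats took in 2044 of 25243 genes (8.10%), and 3 gene lists held more of them. S-phase genes had 8 of 26 bound (30.8%, odds ratio 5.06, adjusted p = 0.0110 by Fisher's exact test over 22 lists): CDT1, E2F1, MCM4, MCM7, RRM2, SLBP, TYMS and UHRF1. Mesenchymal signalling genes had 8 of 27 (29.6%, adjusted p = 0.0110 by Fisher's exact test), with FGF2, HMGA2, LATS2, MET, SKIL, SMAD3, TGFBR1 and YAP1. Immediate early genes had 8 of 30 (26.7%, adjusted p = 0.0155 by Fisher's exact test), with DUSP1, DUSP5, IER5, JUND, KLF2, KLF6, KLF10 and SRF. Bound genes had more run-on counts, with a median of 39 against 12 over the 18 libraries. Among lists matched on run-on counts the 3 lists stood at percentiles 97.6, 99 and 94.4, the last of them inside the range that 95% of matched lists span. In repeat 1 alone S-phase genes (16 of 26) stood at percentile 72.8 and mesenchymal signalling genes (17 of 27) at 96.2, both inside that range, and immediate early genes (24 of 30) at 99.97. Several other lists also stood above the range in repeat 1, as given below. Against genes with at least 1 run-on count, S-phase genes bound in both repeats stood at 97.3, inside that range. Ribosomal protein genes had 2 of 83 bound (2.41%, adjusted p = 0.207 by Fisher's exact test), at percentile 0.02 of the matched lists. The matched lists held a mean of 11.9 bound genes (14.3%). In repeat 1 alone 49 of 83 were bound (59.0%, adjusted p = 4.4e-07 by Fisher's exact test, percentile 94.3), and the genes bound in both repeats are a part of these. Repeat 2 alone was not set against matched lists, and the cause was not tested.

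Of the remaining lists none passed in both repeats. Hypoxia and glycolysis genes had 6 of 27 bound, extracellular matrix genes 7 of 38, Pol II pausing and elongation factors 5 of 30, NF-kB genes 4 of 21, p53 targets 4 of 26, heat shock genes 3 of 15, double-strand break response genes 3 of 31, G2 and M genes 2 of 28, neural markers 2 of 14, SOSS and Integrator genes 1 of 17, cholesterol synthesis genes 1 of 23 and histone genes 1 of 69. ATF4 and unfolded protein response genes (23), R-loop and helicase factors (27), interferon-stimulated genes (35), abundant non-coding RNAs (28), epithelial (18) and leukocyte markers (18) had 0 bound. Among lists matched on run-on counts, which face the same peaks, ATF4 genes stood at percentile 0.86 (matched mean 4.23 genes), R-loop and helicase factors at 1.81 (3.58) and abundant non-coding RNAs at 2.27 (3.26), below the range that 95% of matched lists span. In repeat 1 alone they stood at 98.5, 98.9 and 99.3, above it. Genes bound in both repeats are a part of those bound in repeat 1, and repeat 2 alone was not set against matched lists. These standings therefore do not compare the 2 repeats with each other. Histone (100), immediate early (99.97), cholesterol synthesis (99.75) and hypoxia and glycolysis genes (99.72) also stood above it in repeat 1. So did p53 target (99.61), heat shock (99.58) and G2 and M genes (98.04), while leukocyte markers (0.31) stood below. A high standing in repeat 1 is therefore not particular to single lists. These percentiles are not adjusted over the 22 lists, and the cause was not tested. In the larger repeat 1 alone, 7507 of 25243 genes (29.7%) were bound, among them 18 of 27 R-loop and helicase, 15 of 28 abundant non-coding RNA, 26 of 69 histone, 8 of 35 interferon-stimulated, 4 of 18 epithelial, 18 of 23 ATF4, 18 of 23 cholesterol synthesis and 20 of 26 p53 target genes. Leukocyte markers had 0 of 18 there (adjusted p = 0.00478 by Fisher's exact test). Most other lists also passed in repeat 1, with more genes bound, down to adjusted p = 3.9e-07 by Fisher's exact test for immediate early genes. SOSS and Integrator, NF-kB, histone and interferon-stimulated genes and epithelial and neural markers did not pass.

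**Figure D3:**
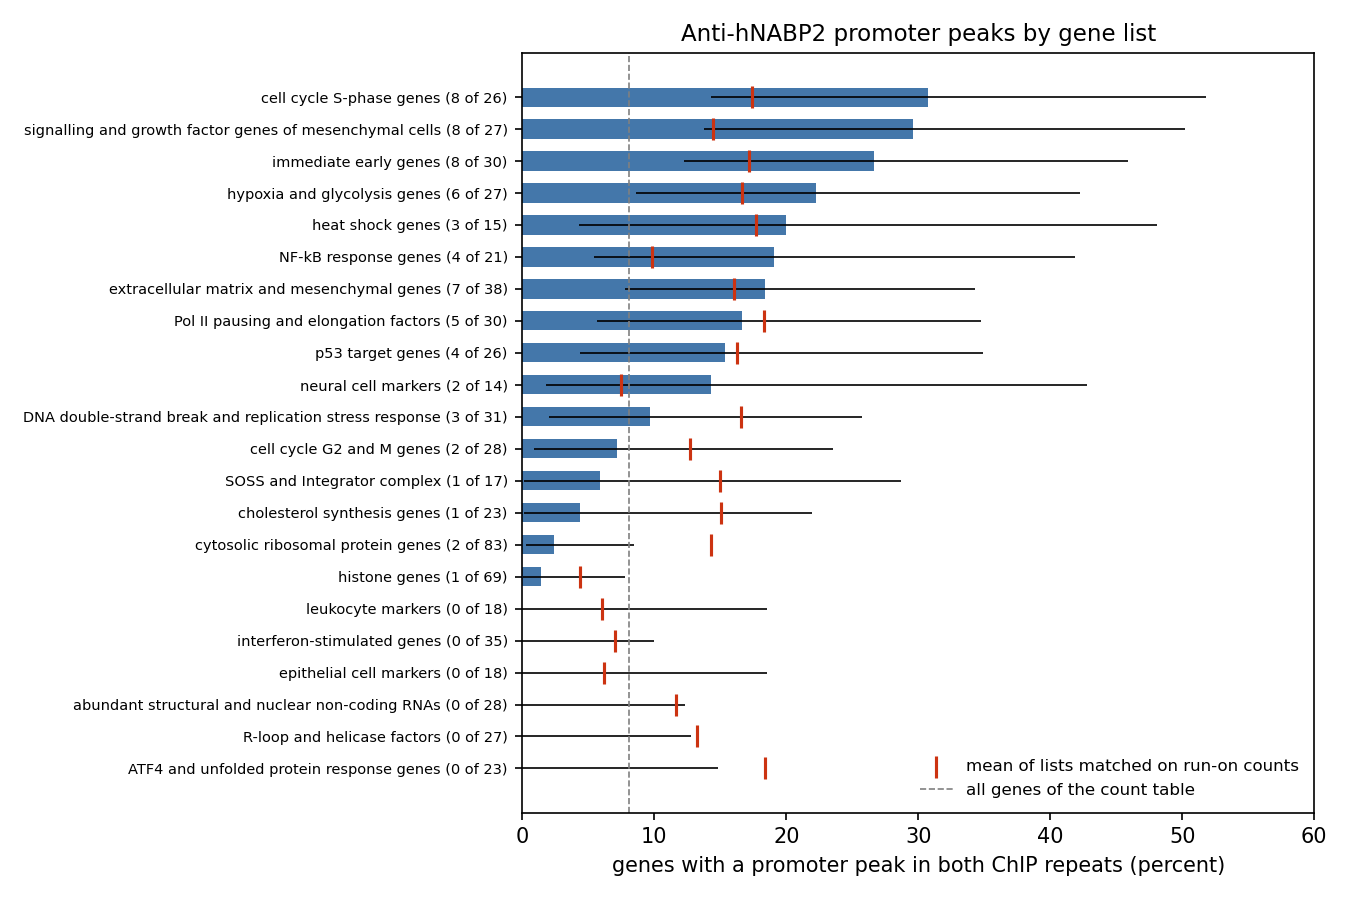
Percent of each list's genes with a promoter peak in both anti-hNABP2 ChIP repeats; bars are percentages with exact 95% binomial intervals, red marks the mean of lists matched on run-on counts and the dashed line all genes of the count table. S-phase, mesenchymal signalling and immediate early genes stand at 30.8%, 29.6% and 26.7% against 8.10% of all genes.

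The next comparison asks whether genes bound by hNABP2 move in libraries labelled hNABP2 KO. Genes bound in both repeats held 14.5 ± 1.88% of run-on counts in WT, 14.1 ± 1.60% with the hNABP2 KO label and 15.3 ± 2.88% with the hNABP1 KO label (SD, n = 3; exact permutation p = 0.8 and 0.7 against WT). Of the 2054 bound genes of the count table, 14 passed the count filter. Their median log2 fold change minus that of the other genes was -0.19 (camera p = 0.923, p = 0.960 with an estimated correlation, fry p = 0.978), at percentile 20.8 of lists matched on expression. Camera's direction was up, against the sign of the medians. The difference ranged from -0.44 without WT repeat 1 (31 bound genes, the 1 case under 0.05 by camera) to 0.25 without WT repeat 3, and was 0.05 without the library labelled hNABP2 KO repeat 1. Among genes with 10 or more counts, the 1947 genes bound in both repeats had a difference of -0.05 with the hNABP2 KO label. This lay at percentile 0 of the matched lists. With the hNABP1 KO label the same genes had a difference of 0.27, at percentile 100. Camera called neither, with the preset or an estimated correlation. These percentiles compare genes, which are not independent replicates, and leave out the spread between libraries. The 48 tested genes bound in repeat 1 had a difference of -0.33 with the hNABP1 KO label (camera p = 0.00575, p = 0.116 with an estimated correlation). The sign reversed among genes with 10 or more counts, where 7012 bound genes had a difference of 0.22 (camera p = 0.0329, p = 0.777 with an estimated correlation).

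Run-on peaks show where the run-on signal was concentrated. Libraries labelled hNABP1 KO had 518, 431 and 9965 peaks in repeats 1 to 3, those labelled hNABP2 KO 243, 338 and 95, and WT 94, 195 and 264. The hNABP1 KO label was above WT in 3 of 3 repeats (3638 ± 5480 against 184 ± 85.5, SD, n = 3; exact permutation p = 0.1, the smallest possible, adjusted 0.45 over 27 tests), and the ratio of means was 19.7, and 2.57 without repeat 3 of that label. Covered length was 1329110 ± 2101780 bp with that label and 49243 ± 26530 bp in WT. With the hNABP2 KO label the mean was 225 ± 122 (exact permutation p = 0.7). These permutations leave out the pairing of the repeats, so their p values are not exact here. In repeat 3 of the hNABP1 KO label, peaks stood at UBE2S, a ubiquitin-conjugating enzyme gene (19, 55407746 to 55408435, fold 128), P4HB, a protein disulfide isomerase gene (17, 81860228 to 81861200, fold 97.7), ACTB and NABP1 (2, 191677876 to 191678229, fold 7.85). Regions at the 45S ribosomal RNA copies RNA45SN2 (21, 8213043 to 8213878) and RNA45SN3 (21, 8396034 to 8396915) and at RN7SL1 (14, 49586591 to 49586870) had peaks in 7 of the 9 libraries.

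**Figure D4:**
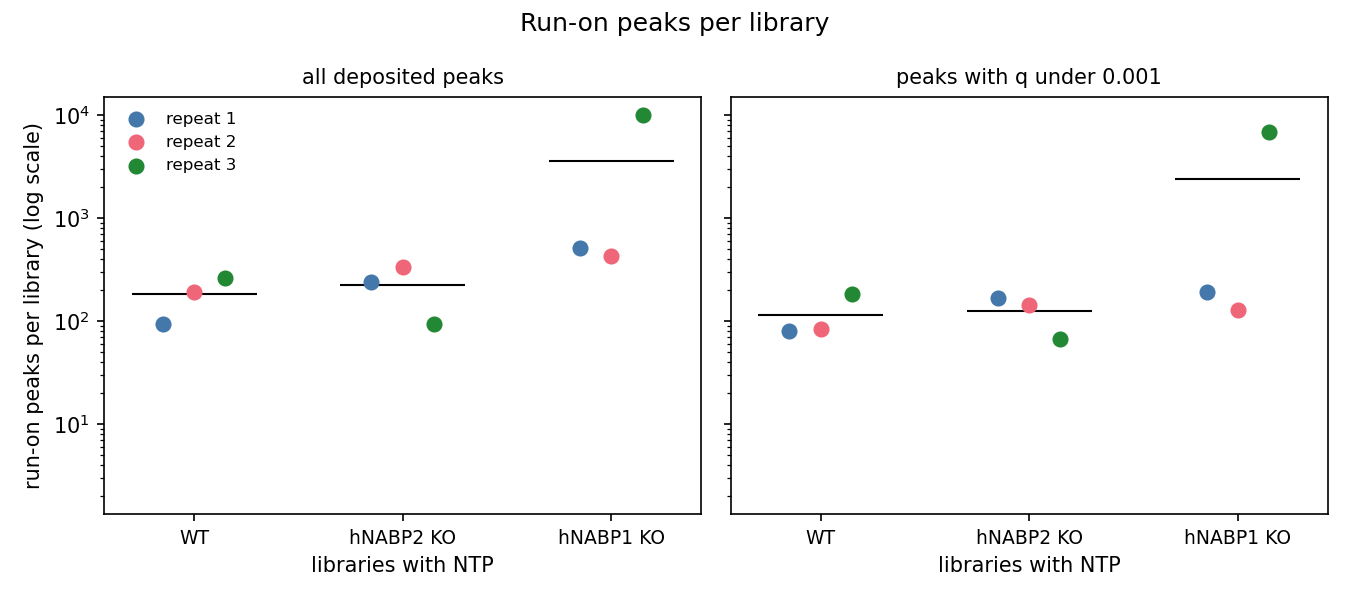
Run-on peaks per library with NTP (log scale), for all peaks (left) and peaks with q under 0.001 (right); points are libraries coloured by repeat and lines are group means. Repeat 3 labelled hNABP1 KO has 9965 peaks, and the other 8 libraries have 94 to 518.

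Run-on peaks lay on hNABP2 ChIP peaks far above random placement on the same chromosomes. Such placement does not match where genes lie. Within 1000 bp of a gene end lay 35.7% to 85.1% of the run-on peaks, and most ChIP peaks. The excess therefore cannot tell hNABP2 sites from gene ends in general. In WT 39.4%, 32.8% and 79.2% of the run-on peaks of repeats 1 to 3 overlapped a ChIP peak, with the hNABP2 KO label 30.9%, 31.1% and 41.1%, and with the hNABP1 KO label 29.9%, 25.5% and 49.0%; random placements gave at most 0.389% on average. The means of 50.4 ± 25.1%, 34.3 ± 5.83% and 34.8 ± 12.5% (SD, n = 3) put both labels below WT, in 3 of 3 repeats each. The exact permutation p was 0.3 and 0.5, where 0.1 is the smallest possible. The share of run-on peaks within 1000 bp of a gene end was lower too. It was 69.3 ± 15.7% in WT, 49.6 ± 7.31% with the hNABP2 KO label and 49.6 ± 12.4% with the hNABP1 KO label. Both labels lay below WT in 3 of 3 repeats (exact permutation p = 0.2 and 0.2). The lower overlap with ChIP peaks therefore cannot be told apart from fewer peaks at gene ends in general. The strongest ChIP peaks on run-on peaks were at MT-TP in the mitochondrial control region (M, 16007 to 16561), ACAP2 (3, 195442471 to 195443414, fold 15.6), LAMP1, TAF4 and PKNOX1.

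DRIP-seq asks where RNA:DNA hybrids form and whether hNABP2 alters them. WT libraries had 173 and 107 peaks and those labelled hNABP2 KO 13 and 167, so the repeats of the KO label differed more than the genotypes did. Between repeats of a genotype 0 peaks were shared in both cases, and 1 peak was shared between WT repeat 1 and repeat 2 of the KO label. In repeat 2 of the hNABP2 KO label the strongest peaks were at the Pol III RNA genes RMRP (9, 35657773 to 35657995, fold 6.24) and RN7SK (6, 52995635 to 52995906, fold 6.28), with others at RN7SL1 (fold 7.26) and RN7SL2 (fold 5.82). Repeat 1 of that label had peaks at MT-RNR2, DDX53, PVT1 and CACNA1A, and WT had peaks at ZNF202, SUGCT and PTK7. In repeat 2 of the hNABP2 KO label 51 of 167 DRIP peaks (30.5%, 95% interval 23.7 to 38.1) overlapped a ChIP peak. Off the contigs and the mitochondrial genome the share was 26.8%, against 0.338% of random placements. With all peaks counted, the other libraries had 10 of 173 (5.78%) and 1 of 107 (0.935%) in WT and 1 of 13 (7.69%) in repeat 1 of the KO label. In repeat 2 of that label 34.5% of the DRIP peaks lay within 1000 bp of a gene end, which random placement does not match. The ChIP peaks that met a DRIP peak with the highest score were at MT-TP, MT-ND6, the growth factor gene CCN2 (6, 131950753 to 131951427), NUCB2 (11, 17276317 to 17276891) and RNA5-8SN3 (21, 8396628 to 8396822). The ratio of mean peak numbers, KO label over WT, was 0.643, and 0.0929 to 1.19 with 1 library of the KO label left out, so the direction rests on single libraries. At q under 0.001 WT had 41 and 12 peaks and the KO label 5 and 83, so the direction reversed with all libraries kept. In WT repeat 2 the median -log10 q (1.30) equalled the lowest, so many of its peaks lay at the weakest value called. With 2 libraries against 2 no p below 0.333 is possible.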

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

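The peaks counted here lie outside the annotation tables and were looked at after the data were seen; no test compares them. Repeat 2 of the anti-hNABP2 ChIP had 12 peaks on an unplaced contig of chromosome 22 that holds ribosomal DNA, and repeat 1 had 0. They drew attention because the comparisons by annotated gene or promoter do not use them. The peak numbers and overlaps given above include them. On the same contig DRIP-seq repeat 2 labelled hNABP2 KO had 5 peaks, where WT repeats 1 and 2 had 1 and 0 and repeat 1 of the KO label had 0. No IgG or RNase H values were analysed here, so no control level stands beside these counts.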

How the results depend on the processing

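The settings with 10 or more counts per gene, without the 2 ribosomal RNA genes, with the peaks of repeat 1 alone, with the replicate block and 1 library left out, and the DRIP ratios without single libraries were chosen after seeing the data; the others were fixed beforehand. Over all results 237 alternative values were computed: 196 kept their direction and side of the threshold, or stayed within the spread, and 41 did not, of which 5 reversed. For run-on genes 102 of 105 stayed, among them 91 of 92 of the settings fixed beforehand, and for peaks 55 of 86. The main count of run-on genes was 0 in each comparison, so those that stayed were again 0. At this depth the simulated test recovered 0% of 4-fold changes, so a count of 0 was likely under most settings. These values are therefore no measure of robustness. With 10 or more counts per gene and the replicate block, 6 genes were called for the hNABP1 KO label and 13 between the knockout labels, and 0 without repeat 3 labelled hNABP1 KO, which holds these counts. The replicate block gave 1 gene for NTP with the hNABP1 KO label, not called without its repeat 3 without NTP; pairing lowered the biological coefficient of variation from 0.717 to 0.338 in the 9 libraries. Gene lists called for the hNABP1 KO label numbered 3 with 10 or more counts by camera (0 with an estimated correlation and 0 by fry) and 2 with the replicate block added; leaving out 1 library gave 0 to 1 list for each label. Without 1 library the difference of hNABP2-bound genes ranged from -0.44 to 0.25 and reversed in 2 cases, to 0.05 without repeat 1 labelled hNABP2 KO and to 0.25 without WT repeat 3; the cause was not tested. Shared ChIP peaks moved from 80.0% to 69.2% with 50% of the peak covered, 54.2% with the stronger 50% of each list (fewer peaks on both sides) and 85.5% with lists widened by 1000 bp. The stronger 50% of repeat 1 lay at promoters in 94.4%. Widening gave 1 DRIP peak shared between repeats, labelled hNABP2 KO. The DRIP ratio of KO label over WT was 0.0929 to 1.19 without 1 library and reversed at 1.19, without repeat 1 labelled hNABP2 KO. It also reversed at q under 0.001 with all libraries kept (41 and 12 peaks in WT, 5 and 83 with the KO label), a setting outside the values counted above. Run-on peak ratios without 1 library were 2.57 to 28.4 for hNABP1 KO over WT, 0.0430 to 0.475 for hNABP2 KO over hNABP1 KO and 0.917 to 1.58 for hNABP2 KO over WT. The last reversed to 0.917 without repeat 2 labelled hNABP2 KO and to 0.982 without WT repeat 1; the cause was not tested. Depth and spread both limit the gene results: the count filter left 129 of 26475 genes, 22428 were tested with no filter, and without pairs the biological coefficient of variation was 1.05 among genes with 10 or more counts, against 0.345 with them.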

Other observations

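Of the tests in this part, those chosen after the results were seen are the antisense share of opposite-strand counting, the library depth behind the run-on peaks, the spread between repeats for weak peaks, the run-on peaks by class of gene, and the settings with 10 or more counts per gene. Peaks at single small RNA genes were looked up after the data were seen, with no test. RPPH1, the RNA of RNase P, had a run-on peak in 5 of the 9 libraries with NTP, all of repeats 1 and 2, with folds of 1.64 to 2.53, and a ChIP peak in repeat 1 (fold 6.66). RN7SL1 had run-on peaks in 7 libraries, RMRP in WT repeat 2 (fold 2.57), and RN7SK in 0. Transfer RNA genes carried 18, 3 and 0 run-on peaks in WT repeats 1 to 3, 28, 8 and 0 with the hNABP2 KO label and 25, 0 and 41 with the hNABP1 KO label. Histone genes carried 5, 0 and 0, 25, 0 and 0, and 9, 0 and 4, with H4C2 among them in WT repeat 1 and in repeat 1 labelled hNABP2 KO. MALAT1 had a ChIP peak at its start in repeat 1 (fold 9.87) and ACTB in both repeats (folds 5.39 and 6.98).

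Repeat 3 labelled hNABP1 KO with NTP held gene counts that no other library did. With genes of 10 or more counts and the replicate block, 6 genes were called against WT: LOC100505841 (222 counts against 1 in WT repeat 3), MAP2K7, a stress kinase gene (278 against 17), UBE2S (202 against 10), P4HB (238 against 16), UBE2V2 (111 against 12) and SFR1 (59 against 4). Between the knockout labels 13 genes were called, the added ones being INTS7, RNF126, TCAIM, HSD17B4, SARAF, THAP7-AS1, MIR3180-5 and LOC105377348. Without this library 0 were called in both comparisons. In the same wider set without the block, S-phase genes had a median log2 fold change of 1.09 with the hNABP1 KO label (24 genes, adjusted p = 6.6e-04 by camera, adjusted p = 0.997 with an estimated correlation, 0.999 by fry). Hypoxia and glycolysis genes (median 0.67) and double-strand break response genes (median 0.67) were also called by camera and had an adjusted p of 0.997 with an estimated correlation. For the hNABP2 KO label 0 of 22 lists were called, with ribosomal protein genes at a median of 0.42 (74 genes).

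Antisense genes held more counts than their sense partners in repeats 1 and 2. The median antisense share over 304 pairs was 67.9% (61.3 to 72.7), and 186 pairs had more antisense counts, such as VIM-AS1 at 4636 against 69 for VIM and PCNA-AS1 at 176 against 0 for PCNA. Others went the other way, such as TTN-AS1 at 1 against 291 for TTN and LRRC75A-AS1 at 5 against 113 for LRRC75A, while repeat 3 stood at 32.4%. This is consistent with counting on the opposite strand in repeats 1 and 2, in which case counts given there for any gene, sense genes such as NABP2 included, may come from its opposite strand. Strong antisense transcription with correct strand assignment stays open: ribosomal protein genes had a median percentile of 80.7 (71.1 to 86.2) among protein-coding genes, an interval that includes the bound of 75 set for it. In repeat 3, with an antisense share of 32.4%, their median percentile was 57.8 (53.8 to 64.7), wholly under that bound. The bound is thus missed where antisense counts do not lead, so this measure cannot tell the 2 explanations apart. No biological explanation was tested.

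More run-on peaks were called with the hNABP1 KO label than in WT in 3 of 3 repeats. The library with the label had fewer gene counts than WT in 2 of the 3 repeats, which argues against depth in gene counts as the cause there. The totals were 11091 against 11981 in repeat 1 and 115528 against 164357 in repeat 3. In repeat 2 the label had more, 7553 against 5883. Gene counts are not the mapped reads behind the peaks, which are not given here, so sequencing depth itself stays open. Weak peaks near the calling threshold stay open for repeats 1 and 2. At q under 0.001 the fold in repeats 1 and 2 together was 1.95 (1.61 to 2.37 by counting error), above the bound of 1.5 set for it, but that bound left out the spread between libraries. The fold fell from 5.51 to 2.39 in repeat 1 and from 2.21 to 1.54 in repeat 2, where the 95% interval of repeat 2 begins at 1.16. In repeat 3, which holds most of the peaks, it went from 37.7 to 37.6, so weak peaks do not carry the excess of that library. An effect of losing hNABP1 remains possible but untested, as do differences between libraries in the control used for calling. Repeat 3 of this label without NTP resembled the repeat 2 libraries, as given below. Whether it served as a control is not given in the sources used here. With NTP, repeat 3 of this label held 7.08% of its counts on RNA45S5 and RNA28S5. WT and the hNABP2 KO label held 0.674% and 0.900% there in repeat 3. How far either departure bears on the peak excess was not tested. The exact permutation p was 0.1, the smallest that 3 against 3 can give, and 9965 of the peaks came from 1 library.

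Repeat 3 labelled hNABP1 KO without NTP resembled the repeat 2 libraries. Thinned to 5272 counts, it correlated with them at 0.537, against 0.307 for WT repeat 3 without NTP, an excess of 0.230 (SD 0.00633 over 20 draws) that depth does not give. It correlated with the other repeat 3 libraries at 0.179, an excess of 0.357 for repeat 2, and its antisense share of 68.3% lay with repeats 1 and 2 (60.5% to 84.6%), outside the 35.4% to 49.8% of the other repeat 3 libraries. A candidate explanation is a preparation shared with repeat 2. No biological explanation was tested.

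Other splits of the libraries were counted for each comparison of run-on genes. In the 3 genotype comparisons and the 3 comparisons of NTP, all 10 splits of the 6 libraries gave 0 genes, the real split included and the highest other split 0; 10 splits are too few for a share under 0.05. For the interactions 100 splits were drawn, and the highest other split gave 4 genes for hNABP2 KO and 0 for hNABP1 KO. With a real count of 0 all 100 splits give as many by construction, so these splits decide nothing.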
